A study of Homo sapiens with 6 samples.

How the data were processed

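RNA sequencing libraries of K562 cells were compared between 3 samples given 20 µM 3FM-dC plus 2 mM THU and 3 samples given DMSO, all for 24 h. K562 is a human line from a chronic myelogenous leukaemia with erythroid features. Per the labels' protocols, the cells were at passages 13 to 16 in a medium with 10% serum, and libraries were made from 1000 ng of total RNA with a directional mRNA kit. The labels name 3FM-dC and THU only by these abbreviations, and no further meaning was assumed. They describe the DMSO in the control group as the solvent of both compounds, so the effects of 3FM-dC and of THU could not be separated.

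The authors deposited raw read counts per gene symbol for each library, and these were used as they stood. STAR, Cufflinks and DESeq2 and the genome build hg19 are listed without roles or versions, per the submitters' processing notes. The counting program, its strand setting, the annotation and the read filters are not given in the sources used here. Each library held counts for 23710 gene symbols and 5 totals of unassigned reads that name no gene. These totals were left out of library sizes and tests. Reads in no annotated feature made up 11.1%, 12.1% and 10.9% of all deposited counts in DMSO replicates 1, 2 and 3, and 11.3%, 11.2% and 13.1% in the treated ones. Ambiguous reads made up between 2.27% and 2.38%. Genes were named by the symbols of the files, and no coordinates were given because the reference annotation at hand was of GRCh38. Exonic lengths from that annotation, matched by symbol, served a single check on weakly expressed genes. Symbols with near-identical copies, including HBG1 and HBG2, HBA1 and HBA2, HSPA1A and HSPA1B, the glycophorins, the histones and the MAGEA and GAGE families, can share reads, and their values are uncertain. Without a stated strand setting, genes that overlap on opposite strands could not be told apart.

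A table of the whole series holds the authors' own comparison of group B with group A, as a fold ratio with its p-value and adjusted p-value, per the file headers. The headers do not name the groups. The authors' deposited table has 17783 rows, of which 2 name no gene and 23 carry a date in place of a symbol. It has no values per library and served only for comparison.

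Genes were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 on the deposited counts, with treatment as the only term. TMM factors scaled the libraries, and filterByExpr with a minimum count of 10 kept 12339 of the 23710 symbols. A gene could pass this filter through a single group. Counts of changed list members below cover only members that passed this filter. P-values were two-sided and adjusted by Benjamini-Hochberg, and an adjusted p under 0.05 counted as a change. Expression is given as CPM, counts divided by the TMM-scaled library size, as mean ± SD of 3 libraries, and the error of a log2 fold change is its standard error (SE). Whole lists of genes were tested with camera of limma 3.58.1, two-sided, with a preset correlation of 0.01 between genes, and adjusted over 32 lists. Camera with an estimated correlation and fry, which tests whether the genes of a list move on balance one way, were run beside it. With an estimated correlation, camera takes its degrees of freedom from the 6 libraries and not from the genes. The same statistic then gives a larger p. The lists, the design and the rule for named genes were fixed before the data were examined. The lists covered DNA methylation and demethylation, nucleotide metabolism, blood lineages, the cell cycle, stress responses, metabolism, chromatin, and markers of lymphoid, fibroblast, endothelial and epithelial cells.

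The rule for named genes took the 6 largest rises and the 6 largest falls among changed genes with a mean of at least 2 CPM and no overlap between groups. It also took the 2 changed members of each list with the smallest p. TET1, TET2, TET3, TDG, DNMT1, DNMT3A, DNMT3B, UHRF1, CDA, DCK, HBG1, HBG2, GATA1, KLF1 and MYC were always named. Other genes, such as the few members that went against their list, were named after their values had been seen. Some genes under this rule and 1 list of genes are not described, and the counts of lists include that list.

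The libraries held between 18408826 and 22750278 counts in genes, at which 3 counts in a library correspond to between 0.136 and 0.168 CPM. A floor of 3 counts per library was used for genes without a DMSO count. With 1 to 3 DMSO counts, ratios carry an exact 95% binomial interval. Such bounds cover counting error only. Replicates were compared in genes with at least 20 counts per pair, where the chi-square per degree of freedom lay between 2.38 and 6.22. All pairs thus differed beyond counting noise and were kept as separate samples, although this spread may be technical and does not show separate cultures.

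The gene test was run on simulated data with the library sizes of these samples and 200 changed genes, and 11900 simulated genes in all passed the filter. It recovered 68% of 50 genes changed by 1.2-fold, 86% at 1.5-fold, 98% at 2-fold and 100% at 4-fold, and 4.87% of its calls were false. The 200 changed genes were balanced in direction and far fewer than the 8198 called in the data, so these rates need not hold there. Camera with the preset correlation called 0 of 30 simulated lists of unchanged, independent genes, and so did the estimated correlation.

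The alternatives were size factors, total counts, no filter and a filter at 5 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, robust dispersions, a replicate block, a minimum fold change of 1.2, an adjusted p under 0.01, and leaving out each library.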

Results

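Gene expression was profiled in K562 cells after 24 h with 20 µM 3FM-dC plus 2 mM THU and after 24 h with the solvent DMSO, with 3 libraries per group. The series title presents the work as one on a small molecule that activates TET2, an enzyme that oxidises 5-methylcytosine, and the design asked which transcripts 3FM-dC alters. DMSO replicates 1, 2 and 3 held 18610733, 18408826 and 22750278 counts in genes. The treated replicates 1, 2 and 3 held 19052821, 20176827 and 20737363. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

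Treated K562 cells had more transcripts of integrated stress response genes and fewer of globin genes than DMSO cells. PHGDH, the first enzyme of serine synthesis, rose 10.3-fold, from 29.2 ± 0.362 to 301 ± 4.75 CPM (SD, n = 3 per group). HEMGN, a nuclear protein of erythroid cells, fell from 356 ± 5.49 to 82.3 ± 3.64 CPM. KLF1, a master regulator of red cell genes, fell from 172 ± 6.10 to 44.9 ± 3.48 CPM. Of the DNA-demethylating enzymes, TET1 fell from 101 ± 8.75 to 33.8 ± 4.30 CPM while TET2 rose from 19.5 ± 2.23 to 24.8 ± 1.02 CPM.

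By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 8198 of 12339 tested genes changed, 4167 of them higher and 4031 lower. With libraries scaled by total counts the split was 5059 higher and 3185 lower. Changes of at least 2-fold were more one-sided, with 1259 genes higher and 303 lower. The CPM values of 8637 genes (70.0%) did not overlap between the groups, against 10% by chance for 3 libraries against 3. The first principal component held 84.1% of the variance and separated the groups.

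Members of the TET and demethylation list went both ways. Of 18 tested members 7 rose, 3 fell and 8 did not pass, and the same number, 10, changed when adjusted over the list alone. TET1 fell (log2 fold change -1.57, SE 0.07, edgeR adjusted p = 3.54e-17), as did TDG, a glycosylase that removes oxidised methylcytosine (-0.31), and IDH3A. IDH1, which makes the TET cofactor 2-oxoglutarate, rose 2.28-fold from 74.1 ± 4.38 to 168 ± 2.64 CPM. TET2 rose by 0.35 (SE 0.09, edgeR adjusted p = 0.00115). TET3 rose by 0.17 (SE 0.07, edgeR adjusted p = 0.0240), a call lost with DESeq2 (adjusted p = 0.0828), without DMSO replicate 3 (0.310) and without treated replicate 3 (0.120), over a range of 0.000704 to 0.989. Against a minimum fold change of 1.2, TET2, TET3 and TDG did not pass (adjusted p = 0.130, 0.989 and 0.166), while the lowest adjusted p over the alternatives was 7.98e-05 for TET2 and 6.28e-11 for TDG. The list as a whole did not pass the set test (camera adjusted p = 0.568).

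Enzymes that write or read DNA methylation were mostly lower. In this list 11 of 15 tested members fell, 1 rose, and 12 changed when adjusted over the list alone. DNMT1, the maintenance methyltransferase, fell from 414 ± 13.1 to 296 ± 11.5 CPM. UHRF1, which brings DNMT1 to replicated DNA, fell by 0.59 on the log2 scale, DNMT3A by 0.46 and DNMT3B by 0.33. USP7, a deubiquitinase, fell from 344 ± 5.95 to 237 ± 16.1 CPM. The list shifted down (camera adjusted p = 0.0160), with an adjusted p = 0.173 with an estimated correlation.

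Genes of nucleotide metabolism were lower in 18 of 32 tested members and higher in 7, with 25 changed when adjusted over the list alone. NME1, a nucleoside diphosphate kinase, fell from 113 ± 6.94 to 68.9 ± 3.82 CPM, and DCTPP1, which hydrolyses dCTP, from 110.3 ± 2.79 to 69.8 ± 3.40 CPM. DCK, which phosphorylates deoxycytidine, had 40.1 ± 3.16 CPM in DMSO and 37.1 ± 2.03 CPM in treated cells (edgeR adjusted p = 0.163). CDA, cytidine deaminase, had 0 counts in all 6 libraries, which allows up to 0.168 CPM per library. The list lay just under the threshold (camera adjusted p = 0.0493; adjusted p = 0.214 with an estimated correlation). It did not pass with total counts (0.0755), with a replicate block (0.0633), with the filter at 5 CPM (0.0621), without DMSO replicate 3 (0.0502) or without treated replicate 3 (0.0607), over a range from 0.000302 with fry to 0.214 with an estimated correlation. Its mean log2 fold change lay at percentile 30.03 and its median at percentile 3.07 among 10000 random lists matched on expression.

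**Figure D1:**
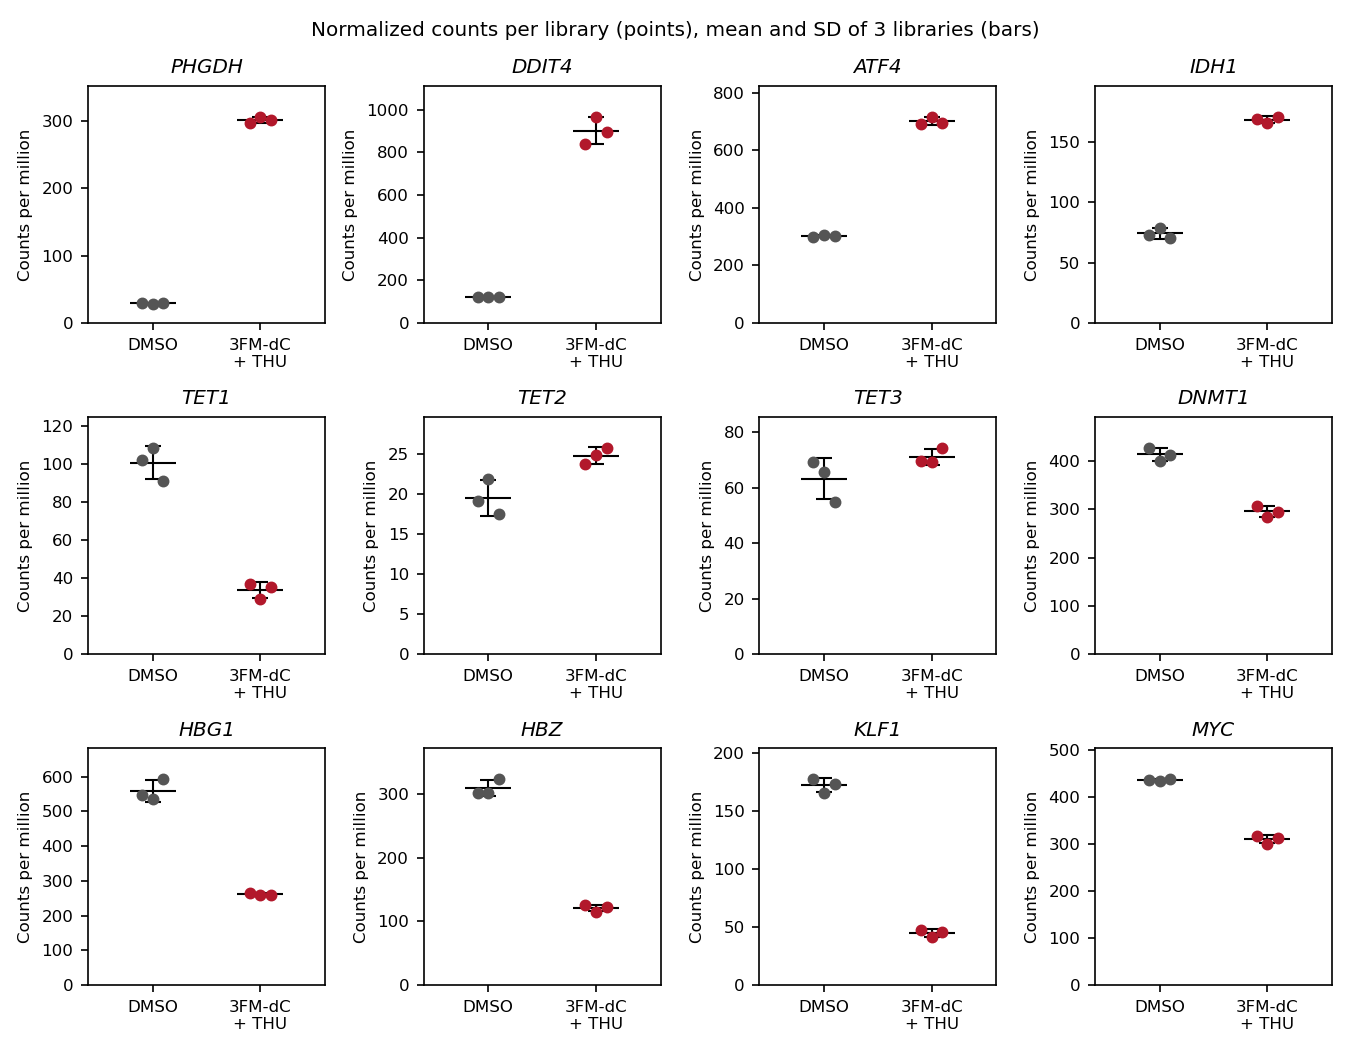
Normalized CPM of 12 genes in each of 3 DMSO and 3 treated libraries (points), with the mean and SD of each group (bars), each axis starting at 0. PHGDH, DDIT4, ATF4 and IDH1 were higher and TET1, DNMT1, HBG1, HBZ, KLF1 and MYC lower in each treated library than in each DMSO library, TET2 rose by 0.35 on the log2 scale, and the groups of TET3 overlapped.

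All 8 tested globin genes fell, the oxygen carriers that K562 makes in embryonic and fetal forms. HBE1 fell from 2666 ± 23.7 to 1325 ± 20.6 CPM and HBZ from 309 ± 12.7 to 121 ± 5.33 CPM. HBG1 fell by 1.10 and HBG2 by 0.95 on the log2 scale, and these near-identical genes can share reads. The median log2 fold change of the list was -1.20 (camera adjusted p = 6.93e-16), and 8 members changed when adjusted over the list alone. The call held with an estimated correlation (adjusted p = 0.0317).

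Other erythroid genes fell in 33 of 42 tested members, with 38 changed when adjusted over the list alone. The erythroid transcription factor GATA1 fell from 263 ± 8.58 to 177 ± 7.87 CPM. GYPE, ALAS2, SLC4A1, GYPB and TAL1 rose instead, by between 0.11 (TAL1) and 0.80 (SLC4A1) on the log2 scale. The list shifted down (camera adjusted p = 1.53e-17), with an adjusted p = 0.0668 with an estimated correlation.

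Myeloid genes moved the other way. Of 34 members 14 passed the count filter. Among these 14, 12 rose, CD68 fell and CEBPD did not pass the test, and 13 changed when adjusted over the list alone. FCGR2A, an antibody receptor, rose from 50.3 ± 1.36 to 103 ± 4.04 CPM, and the transcription factor CEBPB, also a member of the stress list, from 44.4 ± 2.10 to 110.2 ± 7.34 CPM. CSF3R, FCGR1A, KLF4 and CTSG were close to undetected in DMSO and reached between 1.43 (CTSG) and 2.18 (CSF3R) CPM. They had between 0 (CTSG) and 6 (KLF4) DMSO counts in all and passed the count filter only through the treated libraries. The share of risers in this list was therefore partly fixed by the filter. CTSG, with no DMSO count, was at least 9.12-fold higher by a floor of 3 counts per library. The median log2 fold change was 1.22, also with CTSG at that bound (camera adjusted p = 0.000198; adjusted p = 0.0867 with an estimated correlation).

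Of 31 megakaryocyte and platelet genes 15 were tested. These were split, with 5 higher and 5 lower (7 and 5 with total counts), and 10 changed when adjusted over the list alone. RUNX1, a transcription factor of blood stem and platelet cells, rose from 75.2 ± 2.15 to 220.4 ± 15.3 CPM, while TUBB1, a platelet tubulin, fell from 27.8 ± 1.16 to 5.74 ± 0.306 CPM. Of 20 stem and progenitor genes 8 were tested. Of these 8, 3 rose and 3 fell (4 and 3 with total counts), and 6 changed when adjusted over the list alone. GATA2 and MECOM fell by 0.69 and 0.58 on the log2 scale. Their median was above 0 (0.11) while the mean was below (-0.05) and the test pointed down. Neither list passed (camera adjusted p = 0.957 and 0.590).

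The integrated stress response list, targets of the transcription factor ATF4, rose in 36 of 37 tested members, all but CBS, and 28 of them rose at least 2-fold. DDIT4, an inhibitor of mTORC1, rose 7.42-fold. The leucine sensor SESN2 rose from 58.2 ± 1.29 to 362 ± 34.8 CPM, and GDF15, a stress-induced hormone, from 24.6 ± 0.703 to 151 ± 14.0 CPM. SLC7A11, a cystine transporter, rose 3.98-fold, and ATF4 itself rose by 1.21 (SE 0.03) on the log2 scale. The median log2 fold change was 1.77 (camera adjusted p = 3.01e-103), 36 members changed when adjusted over the list alone, and the call held with an estimated correlation (adjusted p = 0.0317).

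Genes of the endoplasmic reticulum and its unfolded protein response rose in 19 and fell in 5 of 28 members (21 and 3 with total counts), with 24 changed when adjusted over the list alone. SEL1L, of the degradation machinery, rose from 51.0 ± 2.83 to 140.0 ± 2.96 CPM, and EDEM1 2.47-fold. SDF2L1, CALR, PDIA6, HSP90B1 and DERL3 fell, by between 0.16 (HSP90B1) and 0.48 (SDF2L1) on the log2 scale. The list shifted up (camera adjusted p = 7.86e-05; adjusted p = 0.173 with an estimated correlation). Heat shock genes fell in 18 of 24 members, with 23 changed when adjusted over the list alone. The abundant chaperones HSP90AB1 and HSP90AA1 fell from 5434 ± 40.9 to 2840 ± 247 CPM and from 3501 ± 59.5 to 1656 ± 180.0 CPM. HSPA6, SERPINH1 and HSF1 rose, HSPA6 by 2.24. This list shifted down (camera adjusted p = 1.03e-09; adjusted p = 0.188 with an estimated correlation).

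Oxidative stress genes of the NRF2 list rose in 17 and fell in 7 of 26 members, and 24 changed when adjusted over the list alone. CAT, the catalase gene, fell 2.26-fold, while SLC7A11, also a member of the stress list, rose 3.98-fold. The list shifted up (camera adjusted p = 0.0107; adjusted p = 0.188 with an estimated correlation). Immediate early genes rose in 18 of 28 members, with 21 changed when adjusted over the list alone. EGR1 rose from 118 ± 5.99 to 343 ± 14.3 CPM and ATF3, also a member of the stress list, 8.66-fold, while ID1, DUSP1 and FOSL1 fell. That list shifted up (camera adjusted p = 3.09e-07; adjusted p = 0.171 with an estimated correlation).

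Apoptosis regulators rose in 16 and fell in 6 of 30 members, with 22 changed when adjusted over the list alone. The death receptor gene TNFRSF10B rose 5.53-fold and BBC3, which encodes the pro-apoptotic PUMA, 3.40-fold. This list shifted up (camera adjusted p = 0.0315; adjusted p = 0.301 with an estimated correlation).

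Of 45 interferon-stimulated genes 26 were tested. Of these 26, 17 rose, and 19 changed when adjusted over the list alone. IFITM1, the most abundant of the changed members, fell from 448 ± 9.96 to 340 ± 3.39 CPM, and BST2 fell by 0.72 on the log2 scale. OAS3, an antiviral RNA sensor, rose from 0.816 ± 0.228 to 6.49 ± 1.91 CPM and IFI35 by 1.33 on the log2 scale. The list shifted up (camera adjusted p = 0.0315; adjusted p = 0.173 with an estimated correlation), and it did not pass with total counts (0.0575, over a range from 0.000199 with fry to 0.173 with an estimated correlation).

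**Figure D2:**
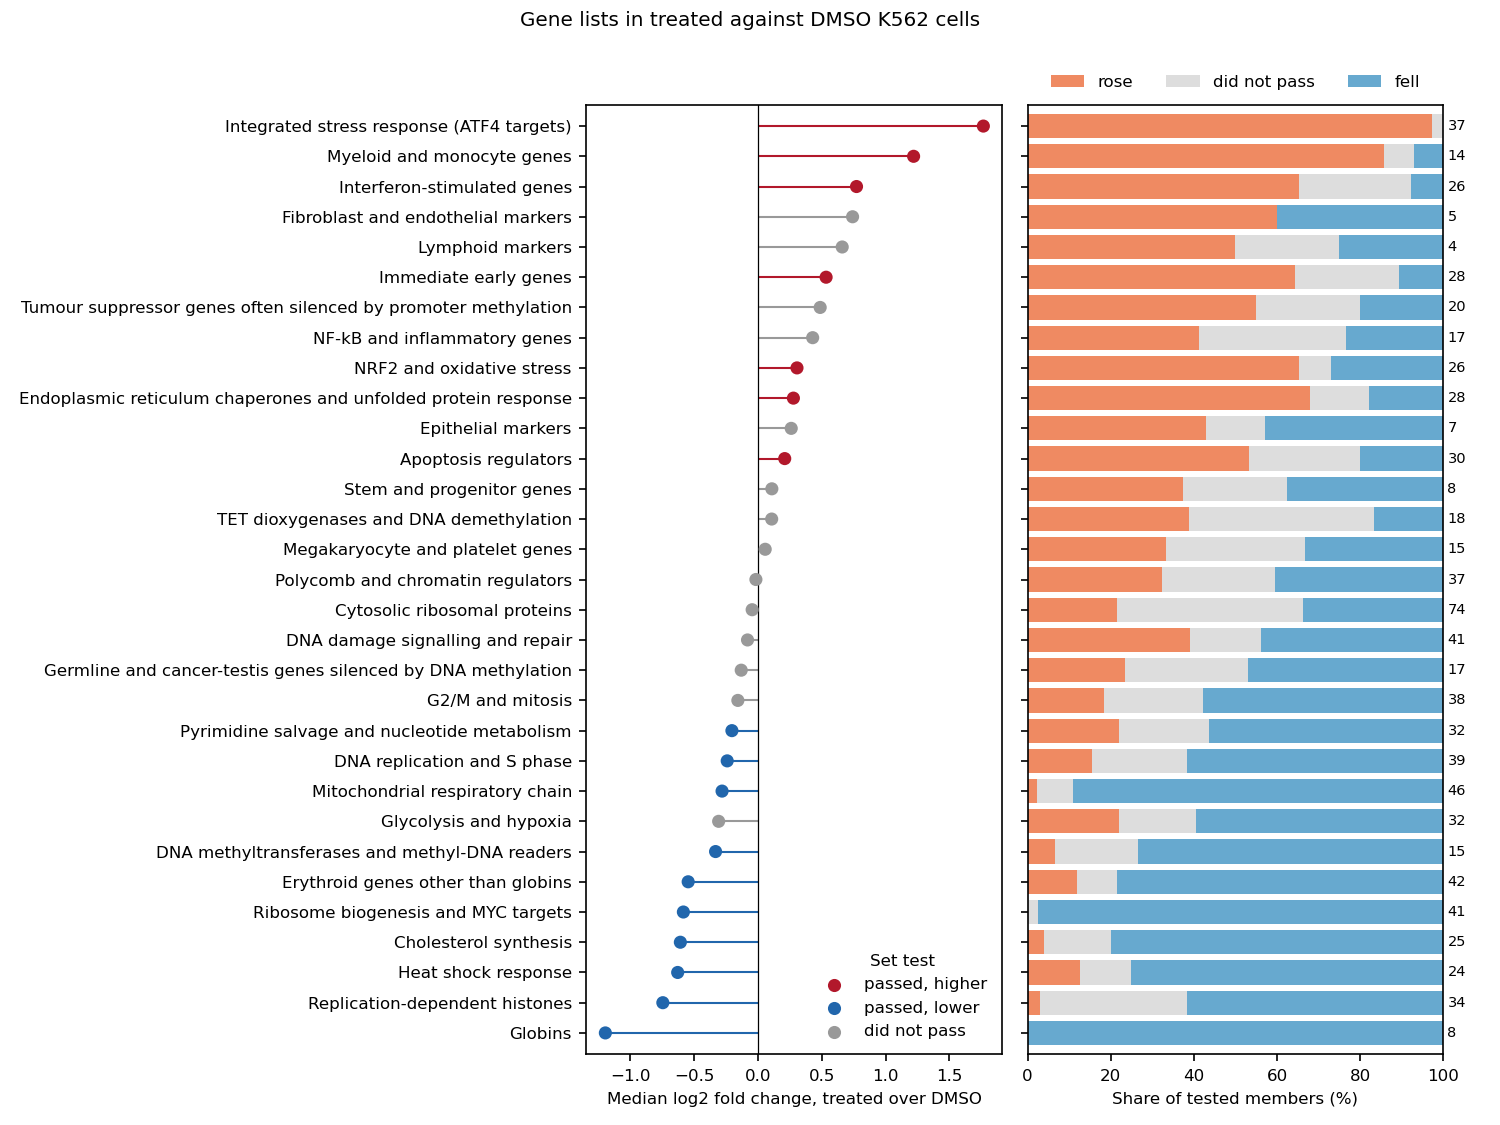
Median log2 fold change of the tested members of each gene list shown, treated over DMSO (left, coloured where camera with the preset correlation gave an adjusted p under 0.05), and the shares of members that rose, did not pass or fell (right, with the number tested). The stress response list lay highest at 1.77 and the globins lowest at -1.20, and the medians of the DNA damage, ribosomal protein and chromatin lists turned positive with total counts.

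In the ribosome biogenesis and MYC target list 40 of 41 members fell, all but RRN3, and 41 changed when adjusted over the list alone. The nucleolar protein NCL fell from 1475 ± 1.63 to 864 ± 68.3 CPM, LYAR by 0.93 on the log2 scale, and MYC from 435 ± 2.19 to 310 ± 8.27 CPM. The list shifted down (camera adjusted p = 1.99e-18; adjusted p = 0.214 with an estimated correlation). Cholesterol synthesis genes fell in 20 of 25 members, PMVK rose, and 21 changed when adjusted over the list alone. HMGCS1, an early enzyme of the pathway, fell from 335 ± 15.1 to 128 ± 7.91 CPM and LSS 2.32-fold. This list also shifted down (camera adjusted p = 8.66e-13; adjusted p = 0.173 with an estimated correlation).

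Respiratory chain genes fell in 41 of 46 members, ATP5H rose, and 44 changed when adjusted over the list alone. These falls were small, with a median log2 fold change of -0.28, as for UQCRH (-0.45) and ATP5B (-0.39). The list shifted down (camera adjusted p = 1.22e-06; adjusted p = 0.214 with an estimated correlation). Of 59 replication-dependent histone genes 34 were tested. Of these, 21 fell, HIST1H4H rose, and 22 changed when adjusted over the list alone. How well the mRNA kit captured these transcripts was not tested. The linker histone HIST1H1C fell from 1065 ± 22.3 to 438 ± 10.2 CPM and HIST1H2BK 2.00-fold. That list shifted down (camera adjusted p = 0.000105; adjusted p = 0.188 with an estimated correlation). DNA replication genes fell in 24 and rose in 6 of 39 members, with 30 changed when adjusted over the list alone. POLD1, a replicative polymerase, fell by 0.55 and the helicase subunit MCM7 by 0.44 on the log2 scale. This list shifted down as well (camera adjusted p = 0.00480; adjusted p = 0.257 with an estimated correlation), and its mean log2 fold change lay at percentile 9.37 and its median at percentile 3.25 among 10000 random lists matched on expression.

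Among the lists that did not pass with camera, mitotic genes fell in 22 and rose in 7 of 38 members (camera adjusted p = 0.112). CCNB1 was lower by a log2 fold change of -0.52 and CDC25C higher by 0.83. The mean of the mitotic list lay at percentile 49.07 and its median at percentile 33.56 among 10000 random lists matched on expression. Its falls were thus no more than those of genes at the same level. Glycolysis and hypoxia genes fell in 19 and rose in 7 of 32 members (0.0603), and without DMSO replicate 3 that list passed (0.0422, over a range from 0.000393 with fry to 0.301 with an estimated correlation). The glucose transporter SLC2A1 fell by 0.89 and the angiogenic factor VEGFA, also a member of the stress list, rose by 1.78 on the log2 scale. Counts adjusted over the list alone were 30 and 26 for these lists.

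Tumour suppressors often silenced by methylation rose in 11 and fell in 4 of 20 tested members, out of 41 listed (camera adjusted p = 0.127). SOCS1 rose from 6.10 ± 1.10 to 24.1 ± 1.33 CPM and SOCS2 2.83-fold, both inhibitors of cytokine signalling, while SOCS3, CDKN1C, APC and BNIP3 fell. Germline and cancer-testis genes fell in 8 and rose in 4 of 17 tested members, out of 40 listed (0.453). GAGE1 was lower by a log2 fold change of -0.95 and MAGEA6 by -0.38. The median of this list was -0.13, its mean 0.00 and the test pointed down. MAEL, MAGEA1, SSX1 and MAGEB1 rose. Adjusted over the list alone, 15 and 12 members of these lists changed.

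NF-kB and inflammatory genes rose in 7 and fell in 4 of 17 tested members, out of 31 listed (camera adjusted p = 0.206). TNFAIP3 was 4.44-fold and the cytokine IL6 10.3-fold higher. SOD2, TNFAIP2, NFKBIA and CD83 fell. DNA damage genes rose in 16 and fell in 18 of 41 members (0.811), and with total counts 18 rose and 12 fell and their median of -0.08 turned to 0.01. BRCA1 rose by 0.71 and PARP1 fell by 0.46 on the log2 scale. Chromatin regulators rose in 12 and fell in 15 of 37 members (0.957), and with total counts 14 rose and 11 fell. The histone demethylase KDM6B rose 2.58-fold. The median of this list was -0.02 against a mean of 0.03 and an upward test, and the median was 0.07 with total counts. Cytosolic ribosomal proteins rose in 16 and fell in 25 of 74 members (0.608). With total counts 30 rose and 5 fell and their median of -0.05 turned to 0.05. Their mean lay at percentile 95.75 and their median at percentile 99.67 among 10000 random lists matched on expression, toward the higher end. RPS26 fell by 0.57 and RPS15 by 0.31 on the log2 scale. Adjusted over the list alone, these 4 lists held 11, 35, 27 and 41 changed members.

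With camera, none of the 3 lists of markers of other cell types passed, while fry called the fibroblast and endothelial list higher (adjusted p = 0.00159), the epithelial list lower (0.0265) and the lymphoid list higher (0.0338). Fibroblast and endothelial markers rose in 3 and fell in 2 of 5 tested, out of 20 listed (camera adjusted p = 0.147). COL6A3 rose from 0.830 ± 0.447 to 30.6 ± 7.27 CPM and COL1A1 3.64-fold. TAGLN was higher and PECAM1 and COL1A2 lower. Epithelial markers rose in 3 and fell in 3 of 7 tested, out of 17 listed (0.608). Their median (0.26) and mean (0.56) were positive while the test pointed down. KRT19 and EPCAM fell by 0.91 and 0.72 on the log2 scale, MUC1 fell and KRT8, KRT18 and ESRP1 rose. ESRP1 had 1 DMSO count in all and a ratio of 60.8 (95% interval 10.5 to 2440). Its fitted log2 fold change of 5.48 weighed heavily on the mean of the list. Lymphoid markers rose in 2 and fell in 1 of 4 tested, out of 25 listed (0.811). CD22 fell by 0.97 on the log2 scale and NKG7 was higher. Counts adjusted over the list alone were 5, 6 and 3.

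Among changed genes with a mean of at least 2 CPM and no overlap between groups, the largest rises were in genes close to silent in DMSO cells. KRT17, a keratin, had 0 DMSO counts and 6.07 ± 2.28 CPM in treated cells, at least 38.7-fold higher by the floor of 3 counts per library. TAC1, a neuropeptide precursor with 1 DMSO count in all, had 0.0185 ± 0.0320 CPM in DMSO and 5.12 ± 1.02 CPM in treated cells. CSTA and MYH15 had 2 DMSO counts each and ratios of 236 (95% interval 65.0 to 1953) and 142 (38.9 to 1176). IL2RB, a receptor chain for interleukins, rose from 0.120 ± 0.0581 to 21.4 ± 3.62 CPM, and SERPINC1, antithrombin, from 0.0929 ± 0.0849 to 13.2 ± 2.89 CPM. Under the same limits, the largest falls were in PPAP2C (4.41 ± 0.429 to 0.431 ± 0.177 CPM), KLF15, ATP1B2, HBBP1, PLCD1 and AQP1. HBBP1, a globin pseudogene, fell 5.89-fold and AQP1, a water channel of red cells, 5.75-fold.

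The direction of change followed the level of expression. Of 823 tested genes with a mean under 1 CPM, 325 rose and 50 fell at least 2-fold. The counts were 634 and 119 of 2667 at 1 to 10 CPM and 250 and 101 of 6293 at 10 to 100 CPM. Above 100 CPM they were 50 and 33 of 2556. The count filter favours weak genes that are high in a single group, so large folds under 1 CPM were partly fixed by it. Without the filter, 70.7% of 6265 genes under 1 CPM with a count had a higher mean in the treated libraries. The median log2 fold change was 0.35 at 1 to 10 CPM and -0.15 above 100 CPM, and with total counts 0.44 and -0.06. Of the rises of at least 2-fold, 16 were in genes without a DMSO count, and all 16 were at least 2-fold by the floor of 3 counts per library.

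**Figure D3:**
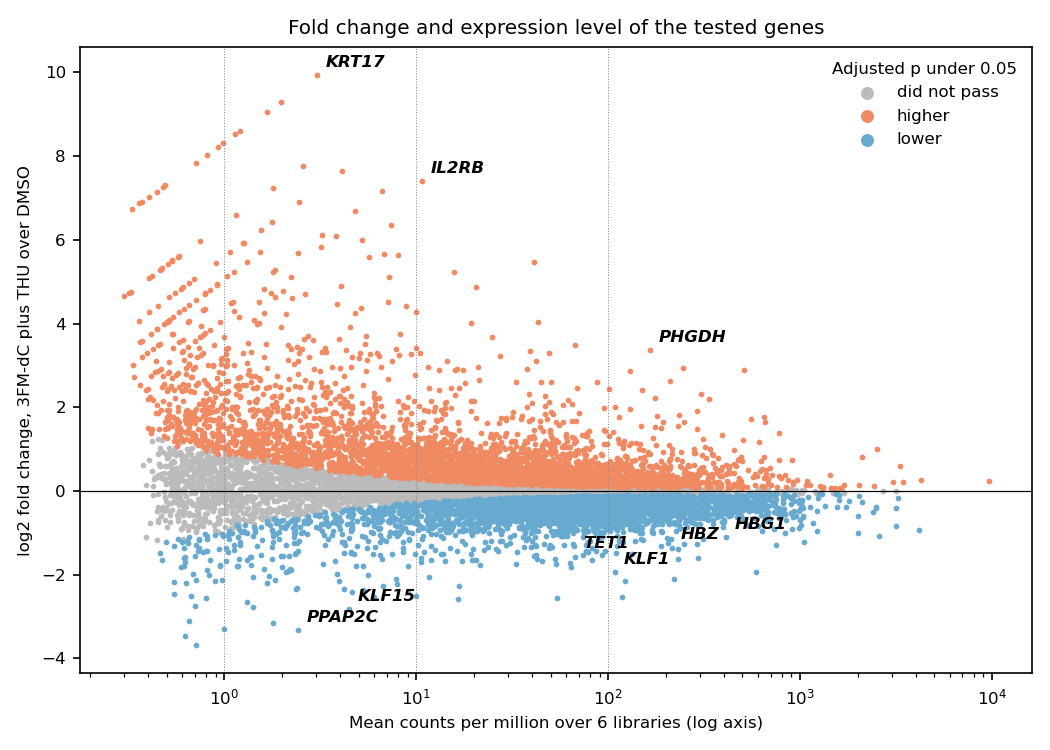
Log2 fold change, treated over DMSO, against mean CPM over 6 libraries (log axis) for the 12339 tested genes, coloured where edgeR gave an adjusted p under 0.05, with dotted lines at 1, 10 and 100 CPM. Rises of 2-fold or more were most frequent at low expression, and genes without a DMSO count, such as KRT17, are drawn at a fitted value that is no bound.

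Camera with the preset correlation called 18 of 32 lists, 8 higher and 10 lower, and with an estimated correlation only the stress response and globin lists passed. Fry called 10 of the lists that did not pass with camera. The control cells received neither compound, so the effects of 3FM-dC and THU could not be separated, and a difference between the groups in culture or preparation was not excluded.

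In the authors' deposited table, 7676 gene symbols had an adjusted p under 0.05, of which 3826 had a ratio over 1 and 3850 a ratio under 1. Of these 7676 in the authors' deposited table, 7419 also changed here, and all 7419 had a ratio on the same side as the log2 fold change of treated over DMSO. Another 257 passed only in the authors' deposited table and 779 only in the test used here. Both comparisons draw on the same series, so their match is no independent evidence. Since the headers do not name the groups, only this match ties group B to the treated libraries.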

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

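The tests of library scaling, of RNA from another cell type and of reads from DNA or unspliced RNA were chosen after the results they bear on had been seen.

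Reads in the genes that the count filter removed drew attention as a signal outside the tested genes. They made up 394 ± 7.95 CPM of the unscaled DMSO libraries and 728 ± 77.3 CPM of the treated ones (SD, n = 3 per group), and each treated library lay above each DMSO library. Weakly expressed genes also rose among the tested ones, with a median log2 fold change of 0.35 at 1 to 10 CPM. One scaling factor per library moves genes of every level alike. The medians at 1 to 10 CPM and above 100 CPM differed by 0.50, which argues against scaling as the cause. The 95% bootstrap interval of 0.47 to 0.53 was taken over genes and leaves out the spread between libraries. RNA from another cell type would bring its abundant transcripts. Among 14 such transcripts, 1 of them above 1 CPM in DMSO, the highest gain was 0.389 CPM (CD3E). In all 6 libraries 8 of them were at 0, which argues against RNA that carries these transcripts. The 14 did not include markers already seen to rise, such as COL6A3 (0.830 to 30.6 CPM), so other sources of RNA were not excluded. Reads from DNA or unspliced RNA stay open beside an effect of the treatment, because the gain of 6265 genes under 1 CPM had a Spearman rho across genes of 0.239 with exonic length (87.3% of them matched to a length), between the bounds set for and against, and a rise of mRNA itself can give such a value, while the shares of reads in no feature overlapped between the groups.

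The mean log2 fold change of the interferon list lay at percentile 97.11 among 10000 matched random lists, and its median of 0.77 at percentile 99.96. The first value lies between the bounds of 95 and 99, so the general rise of weak genes could not be told apart from an interferon response, which remains an untested hypothesis.

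The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 8198 changed genes and the highest of the other splits 0 by edgeR and 0 by DESeq2, with between 30 and 61 genes at an unadjusted p under 0.05 by edgeR, so 1 of the 10 splits gave as many. For gene lists the real split gave 18 and the highest of the others 15, so 1 of 10 gave as many. Each of the other 9 splits called between 10 and 15 lists with the preset correlation although no gene passed. Each of them sets 2 treated libraries and 1 DMSO library against the reverse. Any difference between treated and DMSO libraries thus lies within their groups and partly between them. Neither their gene calls nor their list calls measure what libraries without a difference would give.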

How the results depend on the processing

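Results with at least 2-fold change were added after the data had been seen. Against a minimum fold change of 1.2, 4765 genes changed, 2641 higher and 2124 lower, because this test asks for more than any change. With the filter at 5 CPM in 3 libraries, 568 genes were higher and 169 lower by at least 2-fold, since fewer genes were tested (9934). List calls numbered 2 with an estimated correlation and 28 with fry, which does not compare a list with other genes. The DNA methyltransferase, myeloid and interferon lists lost their calls although their estimated correlations (-0.021, -0.016 and -0.017) lay below the preset 0.01. For these lists this argues against a higher correlation between genes as the cause. The estimated correlation also leaves the test with the few degrees of freedom of 6 libraries, which alone raises its p-values. For the other calls lost with it, this and a higher correlation were not told apart. The other settings kept each count within 1.5 times, and leaving out each library gave 7668 to 8183 changed genes, 3868 to 4153 higher, 3800 to 4030 lower and 17 to 18 lists. No gene called in both the original and another setting changed sign. Of 88 genes under the naming rule, TET3 lost its call with DESeq2 and with 2 left-out libraries, for which the cause was not tested. At an adjusted p under 0.01 it was lost because its edgeR adjusted p was 0.0240. Against a minimum fold change of 1.2, the stricter question left out RPS15, TET2, TET3 and TDG, whose fold changes stayed the same. Replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated at -0.01, 0.00 and -0.06, and not every library correlated best with its own number. The replicate block gave 8050 changed genes, 4091 higher and 3959 lower, and 17 lists, without nucleotide metabolism (0.0633). The planned test of normalized values was not run, because the table of the series holds none per library. Simulated recovery of 68% at 1.2-fold limits statements on small changes, but it came from data with far fewer changed genes and is only a guide.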

Other observations

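The following 8 groups and their tests were chosen only after members had been seen to move, so their p-values are no independent evidence, and none of them passed with an estimated correlation. Proteasome subunits fell in 30 of 31 tested members, with PSMD1 lower by 0.71 on the log2 scale and a median log2 fold change of -0.40 (camera adjusted p = 2.87e-09; adjusted p = 0.120 with an estimated correlation). All 8 subunits of the TCP1 ring chaperonin, which folds actin and tubulin, fell, TCP1 by 0.70 and CCT6A by 0.57 on the log2 scale (camera adjusted p = 2.99e-06; adjusted p = 0.134 with an estimated correlation). Genes of fatty acid synthesis and desaturation fell in 12 and rose in 3 of 15 members, with FADS1 lower by 1.95 and FASN by 1.22 on the log2 scale (camera adjusted p = 3.21e-06; adjusted p = 0.134 with an estimated correlation). Mitochondrial import and chaperone genes fell in 14 and rose in 2 of 20, among them GRPEL1 by 1.27 on the log2 scale (camera adjusted p = 5.34e-06; adjusted p = 0.148 with an estimated correlation).

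Cytosolic enzymes that charge tRNAs rose in 12 and fell in 8 of 20, with WARS higher by 1.64 and MARS by 0.72 on the log2 scale (camera adjusted p = 0.00739; adjusted p = 0.120 with an estimated correlation), and some of them also belong to the stress list. Their mitochondrial counterparts fell in 12 of 17 and rose in 1, EARS2 falling by 0.93 on the log2 scale (camera adjusted p = 0.0181; adjusted p = 0.120 with an estimated correlation). Lysosome and autophagy genes rose in 17 and fell in 8 of 35 (19 and 5 with total counts), with IDS higher by 2.05 and CALCOCO2 by 1.31 on the log2 scale (camera adjusted p = 0.00378; adjusted p = 0.120 with an estimated correlation). Of 390 tested genes with ZNF symbols, which mostly encode zinc finger proteins, 189 rose and 52 fell (230 and 31 with total counts), ZNF117 rising by 1.83 on the log2 scale (camera adjusted p = 0.00736; adjusted p = 0.120 with an estimated correlation). Their median log2 fold change of 0.26 lay above the range of 0.06 to 0.19 that held 95% of random lists matched on expression.

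The mean log2 fold change of the stress response list lay above those of all 10000 random lists matched on expression, and that of the globin list lay below all of them. The mean and the median of the DNA methyltransferase list lay at percentiles 1.11 and 1.65, those of the DNA replication list at 9.37 and 3.25 and those of the nucleotide metabolism list at 30.03 and 3.07.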
